A study of Homo sapiens with 513 samples.

How the data were processed

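Per its labels, the series set out to contrast how NCI-60 lines responded at several times to 15 anticancer agents, and the 513 arrays used here are those of sunitinib. Per the labels' protocols, lines were grown in RPMI-1640 with 10% FBS and plated 24 h before dosing, the vehicle was 0.25% DMSO, and total RNA of quality score above 7.5 was isolated with Qiagen RNeasy columns, labeled with biotin and hybridised in a 96-well format. The deposited table holds 1 value per probeset and array for 22277 probesets, with none missing. How the authors made the deposited log2 values, and whether and how they normalised them, is not given in the sources used here. That the values are log2 and had been brought to a like scale was read from the values alone, which range from 2.34 to 14.0 with array medians of 4.41 to 4.81. No scan dates or batches are given, so no batch could be examined. No genome build is given and no positions are reported.

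Probesets were named by the gene table of the array, with symbols taken from the reference by gene identifier: 19064 probesets named 1 gene, 1043 several genes and 2108 none, and 62 were controls. The probeset with the highest mean over all arrays stood for each of 11963 genes, 4310 of which had several. Groups came from the labels of dose, time, cell line and tissue of origin. Identity was checked by correlation between arrays: 0 arrays matched another line best, and at each time 56 of 56 lines had deviations from the group means that matched best between doses within the line (median r = 0.96, 0.957 and 0.953 at 2, 6 and 24 h, against -0.049, -0.046 and -0.038 between lines).

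Genes were tested with limma 3.58.1 in R 4.3.3, with all 3 doses of a time in 1 fit and the cell line as a fixed block, and called at a Benjamini-Hochberg adjusted p under 0.05. Arrays with vehicle were fitted over time with the same block. Effects between times were tested on within-line differences of differences, and tissues by the F statistic and by contrasts of each tissue with all other lines, on within-line changes at 2000 nM. All tests are two-sided unless stated. Lists of 26 gene groups, the rule for named genes, the comparisons and most alternatives were fixed before the data were examined. Some lists go by short names. Members of the list of MYC and ribosome biogenesis are called MYC targets, and those of NF-kB and inflammatory cytokines NF-kB targets. These names do not mean that each member is a direct target. The shift of a list was tested over lines by 100000 sign-flip permutations, whose smallest p is 1e-05, with adjustment over 26 lists and 6 comparisons with vehicle. Tissue differences of lists were tested by permuting tissue labels, and changes between times by sign flips. Sign flips treat lines as independent and say nothing of correlation among the genes of a list, so each list was also tested with camera, with a preset correlation of 0.01 and with a correlation estimated from the data, and the adjusted p of the latter is given where it ends a call. Receptor levels were the mean of vehicle arrays at the other times, and their relations were tested by permutation with adjustment over 27 relations.

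The named genes of a 2000 nM comparison were the 12 with the largest rise and the 12 with the largest fall among genes that passed and moved the same way in at least 75% of lines. The numbers each way were 5 at 200 nM, 8 for vehicle from 2 to 24 h and 5 for the effect of 2000 nM from 6 to 24 h. For tissues they were the 10 smallest p of the F test and up to 3 genes of each tissue, and for lists up to 4 members. Any receptor could be named. Comparisons outside this rule show genes named elsewhere, chosen after their values were seen. Genes of several probesets are shown by 1 of them, and Y-linked genes and XIST were left out.

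Alternatives to these choices were arrays centred on their medians, quantile normalisation, a filter that left 8735 genes whose 95th percentile exceeded the median of all values, the median of a gene's probesets, all probesets tested singly, no block, per-line pairs, moderation with trend and robust settings, an adjusted p under 0.01, and lists without subtraction or by the median of members. Lines were left out by tissue, singly, where arrays were missing, and where 3 lines are reported to share their origin with another (MDA-MB-435, NCI-ADR-RES and SNB-19). Alternatives added after seeing the data were the removal of 22 arrays with a 3' to 5' difference of ACTB above 1, 7 array quality measures as covariates, and the removal of the 2 h arrays of 2 lines that moved against the panel. Each real grouping was 1 of 100 compared, the others of which exchanged doses within lines, flipped signs per line or permuted tissues. On simulated data, 30%, 86% and 100% of genes changed by 0.1, 0.2 and 0.4 were called for 2000 nM at 24 h, with 6 of 11763 unchanged genes called. For genes changed in leukemia lines alone by 0.4 and 0.8, the F test called 6% and 77% and the contrast with other lines 31% and 96%. A simulated list shift of 0.1 was estimated at 0.084 (adjusted p = 1.04e-03, n = 56 lines), and 0 other lists were called. The simulated noise was drawn independently for each gene and array. How the tests behave with correlated genes, as within the lists, was therefore not covered by these simulations.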

Results

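Gene expression was measured on Affymetrix arrays in 59 established human cancer cell lines of the NCI-60 panel during exposure to sunitinib, an oral inhibitor of receptor tyrosine kinases such as the VEGF and PDGF receptors, KIT, FLT3, RET and CSF1R. Each line was sampled with vehicle (0 nM), 200 nM or 2000 nM sunitinib after 2, 6 and 24 h, and 513 arrays were collected. The vehicle groups held 56, 56 and 57 arrays at 2, 6 and 24 h, the 200 nM groups 56, 58 and 56, and the 2000 nM groups 59, 58 and 57. The lines came from 9 tissues of origin: 6 breast, 6 CNS, 7 colon, 6 leukemia, 9 lung, 9 melanoma, 6 ovarian, 2 prostate and 8 renal lines. All 9 arrays were available for 47 lines. No line had a repeated array at the same dose and time, so the lines are the replicates, each line is its own control, and n counts lines with both arrays of a comparison. The fit of the doses at a time, and so its SE, also used lines that lacked a single dose, vehicle included. Array medians lay between 4.41 and 4.81 (log2), and the number of arrays limits the precision. Changes below are log2 changes within lines, with the standard error (SE) of the fit, for 11963 genes. The shift of a gene list is the mean change of its measured members minus that of all genes, with the standard deviation (SD) over lines.

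The comparison of 2000 nM with vehicle at 2 h addressed the earliest response to the higher dose. DDIT4, a stress-induced inhibitor of mTORC1, rose by 1.12 ± 0.12 (SE, n = 56 lines), or 2.18-fold, and was higher in 52 of 56 lines (adjusted p = 1.01e-12). CHAC1, a glutathione-degrading enzyme induced by ATF4, rose by 1.06 ± 0.12 and was higher in 51 of 56 lines. The kinases CLK1, CLK3 and CLK4, which phosphorylate SR splicing factors, rose by 1.09 ± 0.07 (54 of 56 lines, adjusted p = 7.53e-27), 0.47 ± 0.037 and 0.82 ± 0.07. The transcription factors KLF2 and KLF6 rose by 0.64 ± 0.07 and 0.49 ± 0.05, and the small GTPase RHOB by 0.63 ± 0.08. TSC22D3 and CCNG2, both known targets of FOXO factors, rose by 0.59 ± 0.07 and 0.51 ± 0.06. Expression of the phosphatase gene PPM1B fell by 0.56 ± 0.039 (54 of 56 lines lower, adjusted p = 2.26e-24). SRSF7, an SR splicing factor, fell by 0.31 ± 0.021 (54 of 56 lines lower), and PCF11 and RBBP6, which act in cleavage and polyadenylation of transcripts, fell by 0.50 ± 0.05 and 0.37 ± 0.034. MAFF fell by 0.53 ± 0.07, CXCL8, the gene of interleukin 8, fell by 0.45 ± 0.06, and DUSP5, an ERK phosphatase, fell by 0.36 ± 0.06. In all, 993 genes passed at 2 h, 377 higher and 616 lower, of which 8 rose and 3 fell by at least 0.5. In 2 lines, IGR-OV1 and MDA-MB-231, the changes at 2 h ran against those of the other lines across genes, and without their 2 h arrays 1093 genes passed.

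Of 26 fixed gene lists, 8 shifted at 2 h with 2000 nM by a two-sided sign-flip permutation test. In the ATF4 amino acid stress list, 21 of 40 members rose, none fell and 19 did not pass (28 rose adjusted over the list alone), with a shift of 0.17 ± 0.22 (SD, n = 56 lines), higher in 47 of 56 lines (adjusted p = 4.87e-05, the smallest the permutations can give). Of the 24 transcripts induced by ERK signaling, 18 fell and 6 did not pass (19 fell adjusted over the list alone), among them DUSP6, which fell by 0.49 ± 0.09, and IER3, which fell by 0.35. The ERK list shifted by -0.20 ± 0.25 and was lower in 45 of 56 lines. The FOXO list, with 6 members up, 1 down and 10 not passed (8 and 1 adjusted over the list alone), shifted by 0.11 ± 0.13 and included CDKN1B, the cell cycle inhibitor p27, at 0.30. Of the NF-kB list, 6 members fell and 15 did not pass (11 fell adjusted over the list alone), with a shift of -0.12 ± 0.15. LIF, a cytokine gene on that list, fell by 0.32. The cholesterol synthesis list had 9 of 20 members up and none down (10 adjusted over the list alone) with a shift of 0.076 ± 0.12, and adjusted p = 8.34e-02 with an estimated correlation. Smaller shifts were -0.035 for MYC targets (1 up, 7 down, 17 not passed, adjusted p = 8.66e-02 with an estimated correlation), 0.018 for ribosomal proteins (5 up, 28 not passed, 1.32e-01) and -0.036 for p53 targets (6 down, 14 not passed, 2.39e-01). Adjusted over the list alone, 1 MYC target rose and 9 fell, 9 ribosomal protein genes rose, and 1 p53 target rose and 6 fell.

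At 6 h, the comparison of 2000 nM with vehicle addressed the response after the first hours. INSIG1, which retains the sterol sensor SCAP in the endoplasmic reticulum and is itself a target of SREBP factors, rose by 1.64 ± 0.08 (SE, n = 56 lines), or 3.12-fold, and was higher in 53 of 56 lines (adjusted p = 4.47e-36). MSMO1 and HMGCS1, enzymes of cholesterol synthesis, rose by 1.27 ± 0.06 (54 of 56 lines) and 1.20 ± 0.08 (53 of 56 lines). PCK2, SLC7A11, CTH and PSAT1, which act in mitochondrial phosphoenolpyruvate, cystine, cysteine and serine metabolism, rose by 1.504 ± 0.09, 1.35 ± 0.10, 1.25 ± 0.11 and 1.03 ± 0.07, each in 54 of 56 lines. ASNS, asparagine synthetase, rose by 1.22 ± 0.08 and was higher in 56 of 56 lines (adjusted p = 3.72e-29). DDIT4, CHAC1 and TRIB3, a pseudokinase induced by ATF4, rose by 1.60 ± 0.11, 1.52 ± 0.11 and 1.35 ± 0.09. SRSF7 fell by 0.64 ± 0.031 (54 of 56 lines lower, adjusted p = 1.10e-37) and RBM12, an RNA-binding protein gene, fell by 0.56 ± 0.034. FOSL1 and JUN, subunits of AP-1, fell by 0.54 ± 0.06 and 0.50 ± 0.04, and PLAUR, the urokinase receptor gene, fell by 0.52 ± 0.05. MCM10, a replication initiation factor, fell by 0.52 ± 0.035, CTPS1, which makes CTP, fell by 0.50 ± 0.034, and HK2, a hexokinase gene, fell by 0.53 ± 0.06. At 6 h 3969 genes passed, 1660 higher and 2309 lower, with 48 up and 8 down by at least 0.5.

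With 2000 nM at 6 h, 19 of the 26 lists shifted. Of the ATF4 list, 38 of 40 members rose and 2 did not pass (38 adjusted over the list alone), with a shift of 0.67 ± 0.38 (SD, n = 56 lines), higher in 55 of 56 lines. Its members AARS1 and GARS1, which charge tRNAs, rose by 0.72 and 0.65, and ATF4 itself rose by 0.70. Of 20 cholesterol synthesis genes, 18 rose and 2 did not pass (18 adjusted over the list alone), with a shift of 0.53 ± 0.26 (54 of 56 lines higher). IDI1, an isomerase of that pathway, rose by 0.96 ± 0.04 in 56 of 56 lines. Of 11 fatty acid synthesis genes, 9 rose and 2 did not pass, with a shift of 0.24 ± 0.17, among them the desaturase SCD at 0.74 and the fatty acid synthase FASN at 0.28. Of 32 DNA replication genes, 28 fell and 4 did not pass (29 adjusted over the list alone), with a shift of -0.15 ± 0.10, lower in 54 of 56 lines. Among these, RRM2, a subunit of ribonucleotide reductase, fell by 0.38, and POLE2 fell by 0.31. Of 25 genes of the MYC and ribosome biogenesis list, 23 fell, 1 rose and 1 did not pass, with a shift of -0.18 ± 0.14. On it NOP16, a ribosome assembly gene, fell by 0.42. Of 16 heat shock genes, 12 fell and 4 did not pass (13 fell adjusted over the list alone), with a shift of -0.16 ± 0.14, and the chaperone genes DNAJA1 and HSPH1 fell by 0.41 and 0.35. The counts for fatty acid synthesis and MYC targets were the same adjusted over the list alone.

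The other 13 lists that shifted at 6 h with 2000 nM lost the call with an estimated correlation, whose adjusted p is given for each. Of the ERK list, 17 fell and 7 did not pass, with a shift of -0.18 ± 0.29 (SD, n = 56 lines; 43 of 56 lower, adjusted p = 3.41e-01 with an estimated correlation), and EGR1, an immediate early gene, fell by 0.41. The lysosome list, with 20 up, 1 down and 26 not passed, shifted by 0.084 (50 of 56 lines higher, adjusted p = 5.65e-02 with an estimated correlation), and MAP1LC3B, the autophagosome protein LC3B, rose by 0.47 ± 0.035 in 56 of 56 lines. The FOXO list shifted by 0.12 (10 up, 1 down, 6 not passed, adjusted p = 1.39e-01 with an estimated correlation) and the NRF2 list by 0.10 (10 up, 3 down, 9 not passed, 2.09e-01). On the first of these CCNG2 rose by 0.80 and SOX4 fell by 0.20, and on the other GCLM, a glutathione synthesis gene, fell by 0.15. The NF-kB list shifted by -0.09 (7 down, 14 not passed, adjusted p = 4.96e-01 with an estimated correlation), with CXCL8 at -0.36 and the chemokine gene CCL2 at -0.34. Interferon-induced genes shifted by -0.04 (1 up, 7 down, 23 not passed, 6.56e-01). Targets of the aryl hydrocarbon receptor (AhR) shifted by 0.07 (2 up, 8 not passed, adjusted p = 3.50e-01 with an estimated correlation), epithelial genes by 0.034 (2 up, 15 not passed, 5.64e-01), oxidative phosphorylation by 0.024 (10 up, 2 down, 21 not passed, 4.34e-01) and ribosomal proteins by 0.021 (6 up, 27 not passed, 0.50). For 3 lists the mean and the median of the members differed in sign. ER chaperones shifted by 0.045 with a median of -0.012 (5 up, 4 down, 13 not passed, adjusted p = 7.62e-01 with an estimated correlation), hypoxia genes by 0.04 with a median of -0.015 (10 up, 7 down, 14 not passed, 6.72e-01) and p53 targets by 0.032 with a median of -0.022 (6 up, 5 down, 9 not passed, 7.53e-01). Among these, HERPUD1, induced by ER stress, rose by 0.69, the hypoxia list member STC2, a secreted glycoprotein gene, rose by 0.89, PFKFB3, a regulator of glycolysis, fell by 0.37, and DDB2, a DNA repair gene, rose by 0.41. Adjusted over the list alone, 20 ERK targets fell and 1 rose, 8 NF-kB targets fell, 5 interferon-induced genes fell and 1 rose, 5 ribosomal protein genes rose, 6 ER chaperones rose and 4 fell, and 10 hypoxia genes rose and 8 fell, while the other counts of these 13 lists were the same.

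At 24 h, the comparison of 2000 nM with vehicle addressed the later response. ASNS rose by 1.59 ± 0.09 (SE, n = 56 lines), or 3.0-fold, in 56 of 56 lines (adjusted p = 1.00e-30). PHGDH and PSAT1, enzymes of serine synthesis, rose by 1.07 ± 0.08 and 0.99 ± 0.08, CBS, of cysteine synthesis, by 1.05 ± 0.10, and PCK2 by 1.44 ± 0.10. DDIT4, CHAC1 and TRIB3 rose by 1.45 ± 0.12, 1.35 ± 0.11 and 0.96 ± 0.08, SLC7A11 by 1.22 ± 0.10, and NUPR1, a stress-induced chromatin protein gene, by 1.15 ± 0.14 (49 of 56 lines). The histone gene H2AC6 rose by 1.02 ± 0.08 in 56 of 56 lines. FOSL1 fell by 0.73 ± 0.08 (50 of 56 lines lower, adjusted p = 1.22e-13). SPC25, of the kinetochore, fell by 0.71 ± 0.06, PLK1, a mitotic kinase gene, fell by 0.62 ± 0.05 (53 of 56 lines lower), and MKI67, the gene of the proliferation antigen Ki-67, fell by 0.60 ± 0.05. MCM10 and RRM2 fell by 0.68 ± 0.06 and 0.63 ± 0.04, the latter in 55 of 56 lines. At 24 h 4994 genes passed, 2345 higher and 2649 lower, with 63 up and 17 down by at least 0.5. With arrays centred on their medians 5441 genes passed at 24 h, 1979 higher and 3462 lower, so that the share of higher genes was 36.4% in place of 47%. The array median itself was 0.018 higher with 2000 nM at 24 h, in 44 of 56 lines (adjusted p = 4.62e-03), and the 3' to 5' ratio of GAPDH, a sign of RNA quality, was lower by a log2 difference of -0.05 (adjusted p = 2.53e-02, higher in 18 of 56 lines).

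At 24 h 18 lists shifted with 2000 nM. All 37 mitosis genes fell, with a shift of -0.39 ± 0.33 (SD, n = 56 lines), lower in 53 of 56 lines (adjusted p = 9.06e-02 with an estimated correlation). The mitotic genes CDC20 and PBK fell by 0.49 and 0.50. All 32 DNA replication genes fell, with a shift of -0.33 ± 0.30 (52 of 56 lines lower, adjusted p = 1.19e-01 with an estimated correlation), and the helicase subunit gene MCM4 fell by 0.51. The ATF4 list had 38 members up and 2 not passed (39 up adjusted over the list alone) and shifted by 0.65 ± 0.42, higher in 56 of 56 lines. It was the list that kept its call with an estimated correlation at 2, 6 and 24 h. Of the cholesterol genes 16 rose and 4 did not pass, with a shift of 0.33 ± 0.39 (46 of 56 lines higher, adjusted p = 2.39e-01 with an estimated correlation), among them LSS at 0.58 and FDPS at 0.48. Fatty acid synthesis shifted by 0.20 ± 0.27 (7 up, 1 down, 3 not passed, adjusted p = 2.84e-01 with an estimated correlation), with SCD at 0.78. Of the 47 lysosome genes, 30 rose, 2 fell and 15 did not pass (31 and 2 adjusted over the list alone), with a shift of 0.16 ± 0.13 in 54 of 56 lines (adjusted p = 5.25e-02 with an estimated correlation). TPP1, a lysosomal protease gene, WIPI1, an autophagy gene, and ASAH1, the acid ceramidase gene, rose by 0.53, 0.53 and 0.49. MYC targets fell in 22 of 25 cases, with a shift of -0.21 (50 of 56 lines lower, adjusted p = 2.39e-01 with an estimated correlation). Adjusted over the list alone, 8 fatty acid synthesis genes rose and 1 fell, and the counts for mitosis, DNA replication, cholesterol and MYC targets were the same.

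Among the remaining lists called at 24 h with 2000 nM, the NRF2 list shifted by 0.24 ± 0.24 (SD, n = 56 lines; 15 up, 1 down, 6 not passed, adjusted p = 1.08e-01 with an estimated correlation), with PGD, of the pentose phosphate pathway, up by 0.31. AhR targets shifted by 0.18 (7 up, 3 not passed, adjusted p = 9.81e-02 with an estimated correlation), with CYP1A1, a cytochrome P450 gene induced by that receptor, up by 0.40 ± 0.08 and NQO1 by 0.32. The FOXO list shifted by 0.18 (11 up, 6 not passed, adjusted p = 1.09e-01 with an estimated correlation), with IRS2, an insulin receptor substrate gene, up by 0.30. The ERK list shifted by -0.18 ± 0.24, lower in 45 of 56 lines (15 down, 9 not passed, adjusted p = 3.03e-01 with an estimated correlation), and SPRY4, a feedback inhibitor of the pathway, fell by 0.31. Heat shock genes shifted by -0.17 (12 down, 4 not passed, adjusted p = 8.34e-02 with an estimated correlation) and ER chaperones by -0.07 (4 up, 11 down, 7 not passed, 3.41e-01). On the chaperone list SDF2L1 and MANF fell by 0.47 and 0.38 while HERPUD1 rose by 0.56. Targets of SRF and YAP shifted by 0.11 (8 up, 1 down, 8 not passed, adjusted p = 3.99e-01 with an estimated correlation), with CCN1 up by 0.41 and AMOTL2 by 0.35. Epithelial genes shifted by 0.08 (6 up, 11 not passed, adjusted p = 4.20e-01 with an estimated correlation), ribosomal proteins by 0.045 (20 up, 13 not passed, 2.06e-01), oxidative phosphorylation by 0.024 (14 up, 7 down, 12 not passed, 6.85e-01, and 10 up and 10 down with arrays centred on their medians) and p53 targets by 0.047 with a median of -0.009 (6 up, 6 down, 8 not passed, 7.28e-01). Of the p53 targets, TP53I3 and CCNG1 rose by 0.40 and 0.29 and AEN fell by 0.31. Adjusted over the list alone, 7 AhR targets rose and 1 fell, 13 heat shock genes fell, 4 ER chaperones rose and 12 fell, 22 ribosomal protein genes rose and 1 fell, and 15 oxidative phosphorylation genes rose and 8 fell, while the other counts of these lists were the same.

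The lists that were not called at 24 h with 2000 nM had shifts of -0.008 for hypoxia genes (7 up, 16 down, 8 not passed), 0.0055 for interferon-induced genes (3 up, 4 down, 24 not passed, and 1 up and 6 down with arrays centred on their medians) and -0.06 for NF-kB targets (1 up, 8 down, 12 not passed, adjusted p = 8.40e-02 by permutation). On the hypoxia list STC2 and MXI1, a repressor of MYC targets, rose by 0.89 and 0.47, while the glycolysis genes LDHA and ENO1 fell by 0.20 and 0.15. Of the marker lists of cell types, in which epithelial genes were called, 3 were not: leukocyte genes shifted by 0.01 (2 up, 18 not passed, adjusted p = 7.39e-01 by permutation, and 1 up and 4 down with arrays centred on their medians), melanocyte genes by 0.038 (1 up, 1 down, 10 not passed, 6.07e-01) and mesenchymal genes by -0.031 (5 down, 17 not passed, 0.18). Metallothioneins shifted by -0.06 (3 down, 4 not passed, adjusted p = 2.25e-01 by permutation). The 9 receptors that sunitinib targets shifted by 0.0075, with PDGFRB up by 0.11 ± 0.04 (adjusted p = 1.74e-02), RET down, which fell by 0.09 ± 0.03 (5.83e-03), and 7 that did not pass. With the median of its probesets RET was at 0.0016 (adjusted p = 0.969), and with arrays centred on their medians no receptor passed as higher and 2 passed as lower. The median change of the receptors was -0.0013, of the other sign than their mean of 0.0035. Adjusted over the list alone, 7 hypoxia genes rose and 17 fell, 2 interferon-induced genes and 3 mesenchymal genes fell, 0 leukocyte and 0 melanocyte genes passed in limma, and the NF-kB, metallothionein and receptor counts were the same.

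**Figure D1:**
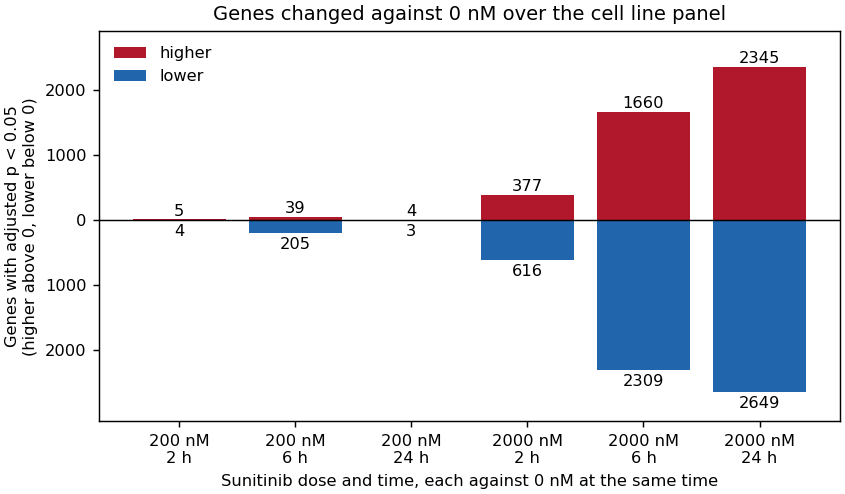
Bars above 0 count the genes higher and bars below 0 the genes lower at the threshold, out of 11963 genes. Each bar compares 200 or 2000 nM with vehicle at the same time. Higher and lower genes together number 993, 3969 and 4994 for 2000 nM at 2, 6 and 24 h and 9, 244 and 7 for 200 nM.

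**Figure D2:**
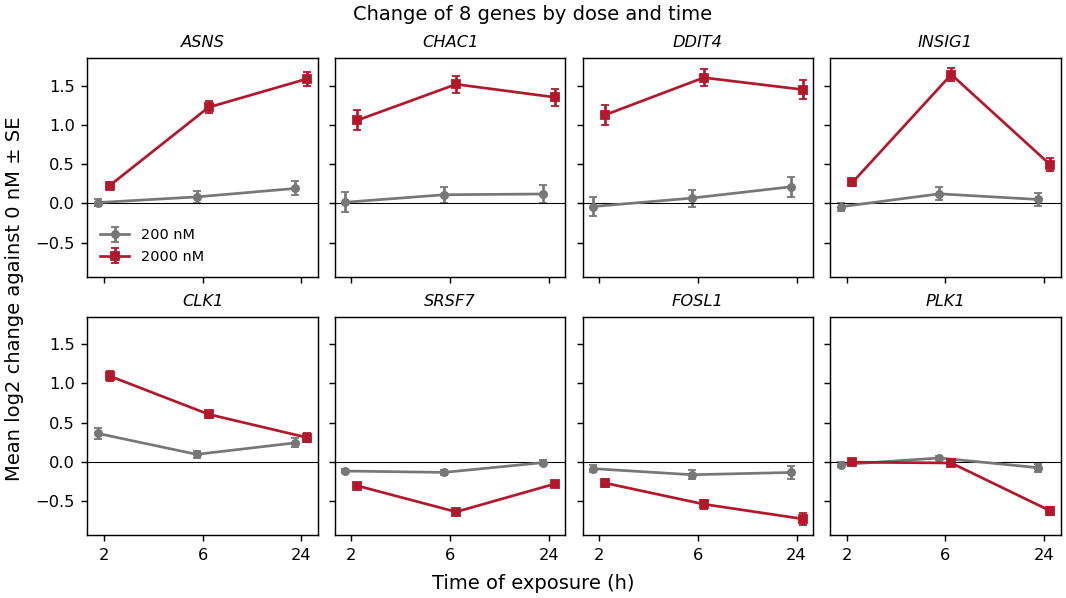
Mean log2 change from vehicle with its SE is plotted against time for 8 genes, with 1 line for 200 nM and 1 for 2000 nM (n = 53 to 56 lines). At 2000 nM ASNS reaches 1.59 at 24 h, INSIG1 peaks at 1.64 at 6 h and CLK1 starts at 1.09 at 2 h.

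The comparison of 200 nM with vehicle addressed the lower dose, at which mean changes over the lines were small. The line KM12 differed at 24 h, with no repeated array. Its changes with 200 nM had a slope of 1.02 on the mean 2000 nM changes of the other lines. That slope, over the 200 genes of largest mean change, had a median of 0.078 over lines. At 2 h CLK1 rose by 0.36 ± 0.07 (SE, n = 53 lines; 45 of 53 higher, adjusted p = 4.23e-03) and CLK3 by 0.20 ± 0.038, while SRSF7 fell by 0.12 ± 0.022 and PPM1B fell by 0.17 ± 0.039. AHCTF1, a nuclear pore gene, fell by 0.12, and CYP2D6 and BMP3 rose by 0.17 and 0.11. These were 7 of the 9 genes that passed at 2 h, 5 higher and 4 lower. At 6 h 244 genes passed, 39 higher and 205 lower. CLK3 rose by 0.21 ± 0.030 in 53 of 56 lines (adjusted p = 6.39e-07), CLK4 by 0.14, and DDB2 by 0.14 ± 0.036. DUSP5 fell by 0.24 ± 0.06 (42 of 56 lines lower) and PHLDA1, another gene induced by ERK signaling, fell by 0.20 ± 0.05. UBP1, a transcription factor gene, and NIPBL, which loads cohesin, both fell by 0.18. At 24 h 7 genes passed, 4 higher and 3 lower. RSRP1, HNRNPA3, NPEPPS and RTN3 rose by 0.22 ± 0.039, 0.14, 0.12 and 0.11, and YAP1, a coactivator of the Hippo pathway, fell by 0.22 ± 0.04 (46 of 55 lines lower). ASNS was not called at 24 h with 200 nM, at 0.19 ± 0.09 (46 of 55 lines higher, adjusted p = 5.65e-01). No gene passed with a change of at least 0.5 at 200 nM in limma, where 1131, 1832 and 1014 genes had an unadjusted p under 0.05 at 2, 6 and 24 h. With quantile-normalised arrays 38.3% of the genes called at 6 h were higher, 82 of 214, in place of 16%. With 7 array quality measures as covariates, added after seeing the data, 78 genes passed at 6 h and 18 at 24 h. At 6 h 75 passed without lung lines and 459 with per-line pairs. At 2 h that share was 33.3% with arrays centred on their medians and 35.3% with quantile normalisation, in place of 55.6%. The control RNA bioB was 0.29 higher with 200 nM at 6 h (38 of 56 lines, adjusted p = 1.65e-02), and at 24 h it was -0.28, with creX at -0.12, 18S at -0.28 and dap at -0.33 (adjusted p = 1.31e-02, 4.45e-02, 4.62e-03 and 5.60e-03, higher in 17, 16, 15 and 11 of 55 lines).

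At 200 nM, 20 of 78 list tests were called. The ERK list shifted by -0.09 at 2 h (45 of 53 lines lower), -0.10 at 6 h (45 of 56) and -0.08 at 24 h (41 of 55), with 0, 2 and 0 members passing over all genes and 4, 9 and 1 falling adjusted over the list alone. With an estimated correlation its adjusted p was 3.57e-02, 8.34e-02 and 8.34e-02 in that order. The NF-kB list shifted by -0.06 at 2 h and -0.05 at 24 h (adjusted p = 3.57e-02 with an estimated correlation at both) and by -0.037 at 6 h (2.79e-01). Cholesterol synthesis shifted by 0.048 at 6 h in 45 of 56 lines with no member past the threshold (adjusted p = 1.44e-02 with an estimated correlation) and by 0.029 at 24 h (2.39e-01). The ATF4 list shifted by 0.05 at 24 h in 39 of 55 lines (adjusted p = 3.57e-02 with an estimated correlation) and by 0.039 at 6 h (1.32e-01). Mitosis genes shifted by -0.032 at 2 h and 0.024 at 6 h (adjusted p = 9.81e-02 and 2.39e-01 with an estimated correlation), and MYC targets and heat shock genes by -0.04 and -0.029 at 6 h (5.65e-02 and 5.25e-02). The other called shifts were p53 targets at 2 h, epithelial genes and ER chaperones at 24 h, and hypoxia genes at all 3 times. Their sizes were -0.034, 0.04, -0.016, -0.017, -0.020 and -0.019, with adjusted p = 8.34e-02, 1.74e-01, 4.47e-01, 5.64e-01, 4.47e-01 and 4.24e-01 with an estimated correlation. Over all genes 1 p53 target fell at 2 h. At 6 h 2 mitosis genes rose, as did 1 p53 target of a list not called at that time, while 2 MYC targets, 2 heat shock genes and 1 hypoxia gene fell. No other member of these lists passed the threshold. Adjusted over the list alone, 3 p53 targets, 2 mitosis genes and 2 NF-kB targets fell at 2 h, 3 mitosis genes rose and 8 MYC targets, 5 heat shock genes and 5 hypoxia genes fell at 6 h, and 1 NF-kB target fell at 24 h.

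Between the doses, 2000 nM against 200 nM, ASNS rose by 1.40 ± 0.09 at 24 h in 55 of 55 lines (adjusted p = 5.79e-26), INSIG1 by 1.52 ± 0.08 at 6 h in 57 of 58 lines, and CLK1 by 0.73 ± 0.07 at 2 h in 54 of 56 lines. SRSF7 fell by 0.50 ± 0.030 at 6 h, and PLK1 fell by 0.55 ± 0.05 at 24 h in 50 of 55 lines. DUSP6 did not differ past the threshold between doses at 2 h, at -0.24 ± 0.09 (adjusted p = 1.20e-01). The genes called were 380 (95 higher, 285 lower) at 2 h, 3365 (1598 and 1767) at 6 h and 4157 (2037 and 2120) at 24 h. The size of the response, the root mean square change over all genes in a line, was larger with 2000 than 200 nM by 0.018 at 2 h (35 of 53 lines, adjusted p = 4.61e-02 by permutation, and 5.64e-02 without 22 arrays of high ACTB 3' to 5' difference), 0.049 at 6 h (52 of 56, 1.50e-05) and 0.08 at 24 h (50 of 54, 1.50e-05). Across genes, which are not independent replicates, the changes at 200 and 2000 nM had r = 0.59, 0.49 and 0.55 at 2, 6 and 24 h, where the shared vehicle arrays alone gave 0.50 at each time in 100 simulations. With the lines split between the doses, so that no vehicle array was shared, r was 0.25, 0.31 and 0.36. Each dose then rested on fewer and different lines, which can also lower r.

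**Figure D3:**
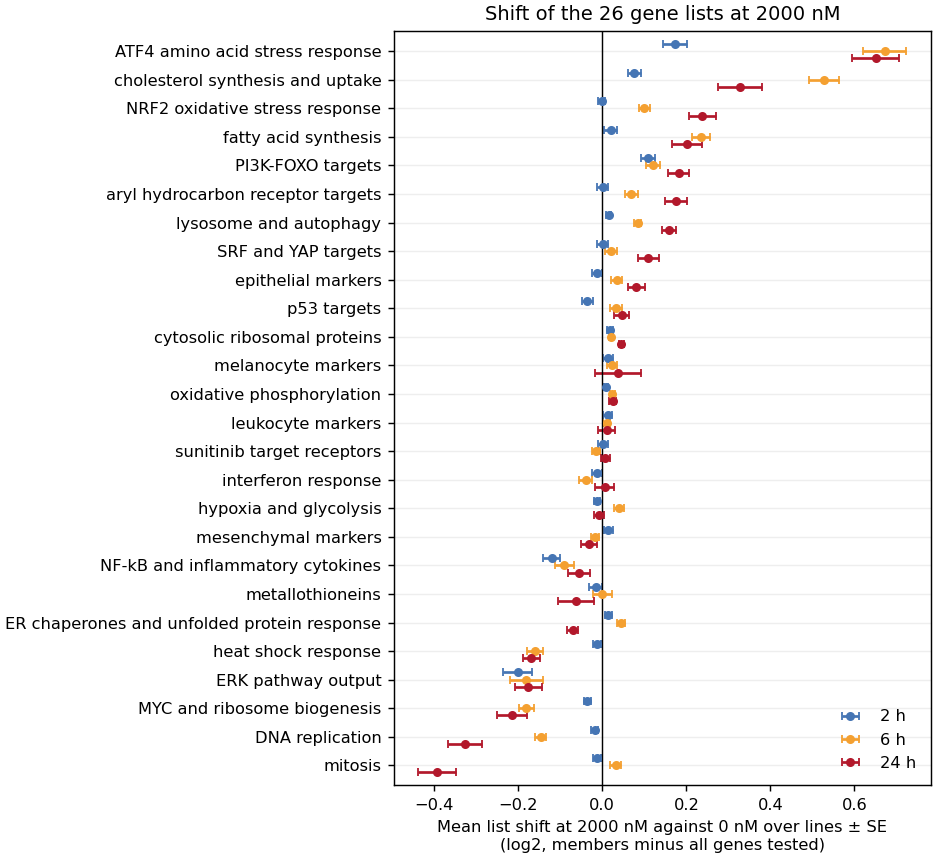
Mean shift (log2) of 26 gene lists with 2000 nM relative to all genes, with the SE over 56 lines, at 2, 6 and 24 h. The ATF4 list reaches 0.67 at 6 h and 0.65 at 24 h, cholesterol synthesis 0.53 at 6 h, and mitosis -0.39 at 24 h.

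The effect of 2000 nM was compared between times within lines. INSIG1 rose from 2 to 6 h by 1.40 ± 0.09 (SE, n = 54 lines; 52 of 54 higher) and from 6 to 24 h fell by 1.20 ± 0.12 (48 of 54 lines lower, adjusted p = 5.28e-11). HMGCS1 and MSMO1 fell by 0.63 ± 0.12 and 0.62 ± 0.09 between 6 and 24 h. The effect on PLK1 fell by 0.62 ± 0.07 in that interval (51 of 54 lines lower), as did CDC25C, a phosphatase gene of mitotic entry, which fell by 0.60 ± 0.07. HMMR, a mitosis gene, was 0.18 above vehicle at 6 h and its effect fell by 0.42 ± 0.05 to 24 h. ASS1, of arginine synthesis, and the splicing factor gene SRSF6 rose by 0.54 ± 0.08 and 0.44 ± 0.033 between 6 and 24 h, the latter in 53 of 54 lines. ASNS rose from 2 to 24 h by 1.39 ± 0.11 in 53 of 53 lines, whereas CLK1 fell by 0.75 ± 0.12. From 2 to 6 h 1734 genes changed in effect (802 up, 932 down), from 6 to 24 h 2186 (1166 up, 1020 down) and from 2 to 24 h 3725 (1677 up, 2048 down). With arrays centred on their medians 38.5% of the genes called from 6 to 24 h were up (864 up, 1383 down), in place of 53.3%. Called at both 6 and 24 h were 2813 genes, 2664 in the same direction. At 200 nM the effect changed from 2 to 6 h for 68 genes (14 up, 54 down), from 6 to 24 h for 97 (70 up, 27 down) and from 2 to 24 h for 1, with 1499 at an unadjusted p under 0.05 in limma. The shares of genes up at 200 nM, 20.6% and 72.2% for the first pair of intervals, were 38.6% and 57.1% with arrays centred on their medians and 43.1% and 51.5% with quantile normalisation.

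As lists, 44 of 78 changes in shift between times were called at 2000 nM by permutation. Cholesterol synthesis rose by 0.47 from 2 to 6 h (51 of 54 lines) and fell by 0.21 from 6 to 24 h (38 of 54 lines lower, adjusted p = 1.04e-03). The ATF4 list rose by 0.50 from 2 to 6 h in 54 of 54 lines and fatty acid synthesis by 0.23 in 51 of 54. Mitosis changed by -0.43 from 6 to 24 h in 51 of 54 lines, after a shift of 0.032 at 6 h that was not called (13 up, 8 down, 16 not passed, adjusted p = 5.05e-02). At 6 h TPX2 and PRC1, of the mitotic spindle, rose by 0.11 each while MKI67 fell by 0.17. DNA replication changed by -0.13 from 2 to 6 h and by -0.17 from 6 to 24 h, and the NRF2 list by 0.10 and 0.13. The smallest adjusted p that the permutations could give was 3.12e-05.

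With vehicle alone, the times were compared as the background of these effects. From 2 to 24 h in culture with DMSO, the immediate early gene ATF3 fell by 0.84 ± 0.09 (SE, n = 54 lines; 47 of 54 lower, adjusted p = 1.00e-14), MAFF fell by 0.85 ± 0.10, and SMAD7 and CCN1 fell by 0.80 ± 0.07 and 0.72 ± 0.10. DLX2, a homeobox gene, fell by 0.98 ± 0.11. DDIT4 rose by 0.66 ± 0.11 in 41 of 54 lines with vehicle, H2AC6 by 0.53 ± 0.08, and IDH1, an isocitrate dehydrogenase gene, by 0.55 ± 0.05. ASNS rose by 0.32 ± 0.06, CHAC1 did not pass at -0.06 ± 0.08, and SRSF6 fell by 0.50 ± 0.034 in 52 of 54 lines. In total 4227 genes passed from 2 to 24 h (2399 higher, 1828 lower) and 2000 from 2 to 6 h (1287 higher, 713 lower).

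Responses to 2000 nM at 24 h were compared among the 9 tissues of origin. The ATF4 list differed among tissues (permutation p = 2.00e-04, adjusted p = 5.20e-03 over 26 lists). Its shift was 1.02 ± 0.22 (SD, n = 8) in renal, 0.87 ± 0.35 (n = 7) in melanoma, 0.85 ± 0.41 (n = 7) in colon, 0.83 ± 0.75 (n = 2) in prostate and 0.81 ± 0.54 (n = 6) in ovarian lines. It was 0.50 ± 0.32 (n = 9) in lung, 0.47 ± 0.13 (n = 6) in leukemia, 0.28 ± 0.23 (n = 6) in breast and 0.13 ± 0.10 (n = 5) in CNS lines. The melanoma, ovarian and CNS groups include MDA-MB-435, NCI-ADR-RES and SNB-19, which are reported to share their origin with another line. These SDs and the permutation count them as independent lines. Heat shock genes also differed (adjusted p = 1.08e-02 by permutation), from a shift of -0.30 in leukemia and in colon to -0.05, -0.04 and -0.03 in breast, CNS and ovarian lines. Leukocyte markers came next and were not called (5.37e-02). Among genes, 190 differed among tissues at 24 h and 38 at 6 h by the F test of limma (109 and 18 without 3 lines of shared origin, 93 and 20 in lines with all 9 arrays), led at 24 h by RALB, a RAS-like GTPase gene (F = 8.89, adjusted p = 1.53e-03), with changes of 0.68 in leukemia and -0.20 in renal lines. ATM, the kinase of the DNA damage response, changed by 1.03 in leukemia lines.

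Each tissue was also compared with all other lines in its response to 2000 nM at 24 h, in limma. Leukemia lines differed at 646 genes, 340 higher and 306 lower: TM6SF1 changed by 1.54 ± 1.11 (SD, n = 6) against -0.016 elsewhere (adjusted p = 6.65e-07), and EDEM1, of ER-associated degradation, by 0.62 against -0.10. Without the line SR this count was 137. Colon lines differed at 61 genes, 48 higher and 13 lower, among them CLIC4, a chloride channel family gene, at 1.44 ± 0.67 (n = 7) against 0.43 (adjusted p = 6.61e-04) and TJP3, of tight junctions, at 0.66 ± 0.53 against -0.0065 (2.05e-04). The colon count was 22 without HCT-15, 20 without HT29, 11 without KM12, 36 with arrays centred on their medians and 25 with quantile normalisation, and with median-centred arrays 63.9% of colon genes were higher in place of 78.7%. Melanoma lines differed at 33 genes, 18 higher and 15 lower, with BEST1, a chloride channel gene, at 0.91 ± 0.54 (n = 7) against 0.021 (adjusted p = 4.11e-07) and DDR2, a collagen receptor, at 0.96 ± 0.45 against 0.034 (2.13e-06). The melanoma count was 56 without LOX, 17 without M14 and 20 without SK-MEL-2. Renal lines differed at 31 genes, 13 higher and 18 lower: BCAT1, of branched-chain amino acid metabolism, changed by 0.92 ± 0.23 (n = 8) against 0.07 (adjusted p = 6.44e-03) and the adhesion receptor gene CD44 by -0.73 ± 0.34 against -0.11 (8.09e-03). The renal count was 6 without ACHN, 19 without CAKI-1, 53 without A498 and 16 without the renal line whose name is written in digits, and the renal share of higher genes was 58.6% with median-centred and 59.3% with quantile-normalised arrays in place of 41.9%. The single gene of the prostate lines was SLCO1B3, an organic anion transporter, at -1.32 ± 0.52 (n = 2) against -0.07 (adjusted p = 3.90e-02 in limma). Breast, CNS, lung and ovarian lines gave 0 genes in limma, with 611, 850, 335 and 961 at an unadjusted p under 0.05. Ovarian lines gave 2 genes with the expression filter. Without 3 lines of shared origin (MDA-MB-435, NCI-ADR-RES and SNB-19) the counts were 25 for ovarian, 29 for colon, 19 for melanoma, 20 for renal and 0 for prostate lines.

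**Figure D4:**
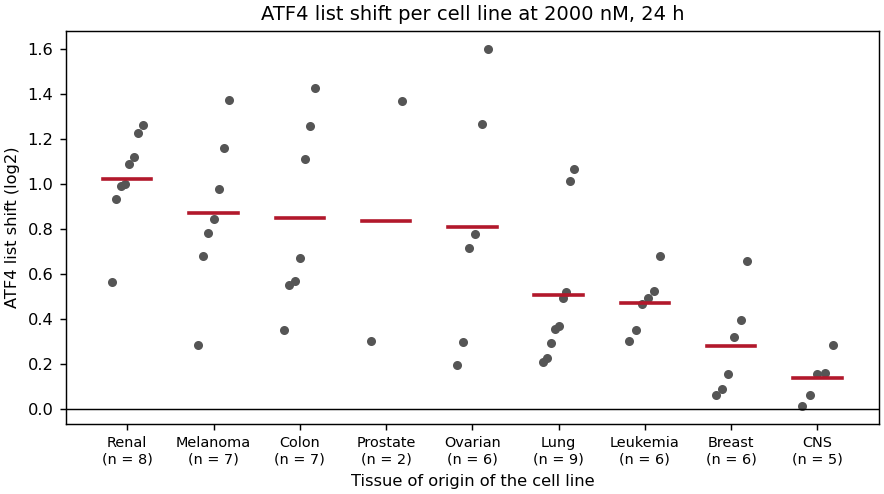
Shift of the ATF4 list (log2) at 24 h with 2000 nM for each line, grouped by tissue of origin, with a red bar at the tissue mean. Renal lines average 1.02 and CNS lines 0.13.

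The relation of receptor expression to the early fall of ERK targets was examined because the receptors are the drug's intended targets. In vehicle arrays, KIT exceeded the median of all values (4.6) in 6 lines and was highest in MALME-3M at 8.36, PDGFRA and FLT4 did so in 5 lines each, KDR, RET and CSF1R in 3 each, PDGFRB in 2, and FLT1 and FLT3 in 1 each. Of 27 relations between a receptor's vehicle level and the ERK list shift (9 receptors at 3 times), 0 were called by permutation with Pearson's r or with Spearman's rho. Each relation needed vehicle arrays of a line at both other times. MALME-3M, with arrays at 2 h alone, therefore entered none of the 27. The same holds for U251, the line highest in PDGFRA, which lacked a vehicle array at 2 h. The unadjusted p was under 0.05 for 1 relation with r and for 2 with rho, all at 2 h. PDGFRB had r = -0.289 (p = 4.43e-02, adjusted 4.64e-01, n = 53 lines) and rho = -0.303 (p = 2.74e-02, adjusted 3.70e-01). PDGFRA had rho = -0.349 (p = 1.10e-02, adjusted 2.97e-01, n = 53 lines) and r = -0.258 (p = 6.24e-02, adjusted 4.64e-01). Without the 2 lines farthest from the median r was -0.262 for PDGFRB and -0.304 for PDGFRA.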

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

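The 3 tests of explanations for the ATF4 difference among tissues were written before their results were seen, and no test in this part was chosen after the result.

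The rise of the ATF4 amino acid stress list with 2000 nM at 24 h differed among tissues (adjusted p = 5.20e-03), from 1.02 in renal to 0.13 in CNS lines. Noise of the 24 h arrays was argued against by tissue means at 6 h, measured on other arrays, which followed those at 24 h (rho = 0.733, exact one-sided permutation p = 1.56e-02, and r = 0.777, 7.89e-03, over 9 tissues, with r = 0.680 without the 2 tissues farthest from the median). A different vehicle level of the list was argued against as a whole explanation, because the difference remained after a fit on it (permutation p = 7.80e-04, against 2.00e-04 without it). The difference also remained after a fit on the root mean square change of all other genes (permutation p = 4.40e-04). That measure is a poor guide to the response. At 24 h it averaged 0.22 over lines with 200 nM, where 7 genes passed, and 0.30 with 2000 nM. A larger response of all genes in some tissues therefore stays open. Differences of tissue, of uptake or metabolism of the drug, and of growth rate were not tested, and with no dates given, a batch that follows tissue stays open. A tissue difference in how strongly sunitinib engages this stress response is therefore a hypothesis only, which may rest on any of these.

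Other differences between tissues met the test of the difference itself. Heat shock genes differed among tissues with adjusted p = 1.08e-02. At 24 h 190 genes differed among tissues and at 6 h 38. Against all other lines the counts were 61 genes for colon, 646 for leukemia, 33 for melanoma, 31 for renal and 1 for the 2 prostate lines. In the renal group A498 was flagged as an outlier, with an ATF4 list shift of 0.562. It was the 1 flag in 16 groups tested. Chance flags about 1 group in 20, so a single flag is no more than chance may give.

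Between times, the effect of 200 nM differed at 68 genes (2 to 6 h), 97 genes (6 to 24 h) and 1 gene (2 to 24 h), and that of 2000 nM at 1734, 2186 and 3725 genes. Of the lists, 44 shifts differed between times at 2000 nM. From 2 to 6 h these included 0.468 for cholesterol synthesis, 0.229 for fatty acid synthesis and 0.499 for the ATF4 list, and from 6 to 24 h -0.211 for cholesterol synthesis and -0.428 for mitosis. From 2 to 24 h they included 0.275 for cholesterol synthesis, 0.484 for the ATF4 list, -0.323 for DNA replication, -0.390 for mitosis and 0.246 for the NRF2 list.

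Probesets outside the gene table also changed with 2000 nM at 24 h against vehicle: 429 of 1043 that match several genes (252 higher, 177 lower) and 546 of 2108 with no gene named (270 higher, 276 lower).

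Regrouping the arrays argued against chance for most counts, to no finer than 1 in 100 and without adjustment over the counts. Of 100 groupings, the real one included, 1 gave as many genes as the real one for each of the dose comparisons. For 200 nM the real counts at 2, 6 and 24 h were 9, 244 and 7 and the highest others 2, 1 and 1. For 2000 nM they were 993, 3969 and 4994 against 114, 201 and 2380, and for 2000 against 200 nM 380, 3365 and 4157 against 1, 34 and 187. With vehicle they were 2000 against 10 (2 to 6 h) and 4227 against 733 (2 to 24 h). For effects between times, 1 of 100 reached the real count for 2000 nM (1734, 2186 and 3725 against 1, 1 and 3) and for 200 nM at 68 against 0 and 97 against 10. From 2 to 24 h at 200 nM, 5 of 100 reached the real count of 1 (highest other 4), so chance was not argued against. Among tissues 1 of 100 reached 190 at 24 h (highest other 15) and 38 at 6 h (22), as for leukemia (646 against 35), melanoma (33 against 5) and renal lines (31 against 5). For colon 3 of 100 reached 61, and the highest other was 787. For breast, CNS, lung and ovarian lines the real count was 0, which any grouping reaches, so the comparison could decide nothing there. The highest others were 35, 729, 31 and 15. A regrouping with several times the colon count points to a structure of the lines, which was not examined. The count of the prostate group, which holds 2 lines, was not compared with regroupings.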

How the results depend on the processing

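Removal of arrays by ACTB, the array quality covariates and removal of the 2 h arrays of 2 opposed lines were chosen after the result was seen, and the other settings were planned. Effects of 2000 nM held best: the counts at 6 and 24 h, 3969 and 4994, stayed within 1.5 times under every setting but 1, the fit with no block. Leaving out 1 line at a time gave 883 to 1140 genes at 2 h, 3863 to 4026 at 6 h and 4853 to 5122 at 24 h for 2000 nM. No list call changed direction under the list alternatives run. Centring arrays on their medians cannot change a list shift, which subtracts the mean of all genes, so all 65 list calls held by construction. Of the 65, 64 held with quantile normalisation, 54 without colon lines, 55 by the median of members and 56 without renal lines. Most counts that moved were small ones, for 200 nM or single tissues. Unless stated, the cause was not tested. Of 11963 genes, 3228 lay below the expression filter, and how signal over background limits the detection of small changes was not tested.

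With no block for the cell line, so that differences between lines enter the spread and pairing is lost, 200 nM gave 0, 0 and 0 genes at 2, 6 and 24 h, 2000 nM gave 8, 81 and 75, 2000 against 200 nM gave 3, 49 and 38, and vehicle gave 7 (2 to 6 h) and 23 (2 to 24 h). COL1A1 at 24 h turned to 0.0093 (adjusted p = 1.00 without the block, against -0.11 ± 0.04 with it). With per-line pairs 200 nM gave 30, 459 and 68.

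With arrays centred on their medians, 200 nM at 2 h gave 15 genes, its effect from 2 to 6 h 44 and from 2 to 24 h 4, and colon 36. Quantile normalisation gave 17, 2 (2 to 24 h) and colon 25. The expression filter gave 146 for the 200 nM effect from 6 to 24 h and 2 for ovarian lines. The median of probesets gave 4, 146 and 12 for 200 nM and 42 for its effect from 2 to 6 h, and it turned RET and RPS14 at 24 h to 0.0016 (adjusted p = 0.969) and -0.023 (0.673) because other probesets entered. All probesets singly, more features by construction, gave 15 for 200 nM at 24 h, 6450 for vehicle from 2 to 24 h, 38 and 12 for the 200 nM effect from 2 to 6 and 2 to 24 h, colon 39, prostate 0 and renal 51.

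Without 3 lines of shared origin the counts were 4 for 200 nM at 24 h, 51 and 13 for its effect from 6 and from 2 to 24 h, 109 and 18 among tissues at 24 and 6 h, colon 29, melanoma 19, ovarian 25, prostate 0 and renal 20. Lines with all 9 arrays, fewer by construction, gave 117 for 200 nM at 6 h, 36 and 48 for its effect from 2 to 6 and 6 to 24 h, 93 and 20 among tissues, and ovarian 1. For 200 nM at 6 h the count was 116 without breast, 151 without colon, 75 without lung, 150 without melanoma, 158 without ovarian and 141 without renal lines. For 200 nM at 2 h it was 5 without CNS, 5 without leukemia and 17 without melanoma lines, and at 24 h 11 without CNS, 2 without colon, 4 without lung, 3 without melanoma and 2 without renal lines. Without renal lines 2000 against 200 nM at 2 h gave 245.

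Moderation with trend and robust settings gave 24 and 59 for the 200 nM effect from 2 to 6 and 6 to 24 h. At an adjusted p under 0.01, stricter by construction, 200 nM gave 5, 74 and 2, 2000 nM at 2 h 513, 2000 against 200 nM at 2 h 190, vehicle from 2 to 6 h 1140, the 200 nM effect 15 and 22, the 2000 nM effect 1008 and 1315, tissues 29 and 12, colon 8, leukemia 157, melanoma 17, prostate 0 and renal 9. Without the 22 arrays of high ACTB difference, 200 nM gave 5 and 4 at 2 and 24 h, its effect 28 and 61, ovarian 1 and prostate 0, and the response size difference at 2 h was 0.018 (adjusted p = 5.64e-02, no longer called). With quality covariates 200 nM gave 78 at 6 h and 18 at 24 h. Without the 2 h arrays of 2 opposed lines it gave 14 at 2 h and 2 for its effect from 2 to 24 h. With an estimated correlation 16 of 65 list calls held.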

Other observations

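The groups of splicing, histone and KLF genes, the tests of paralog probes and of feedback for CLK genes, and all tests on the 2 opposed lines were chosen after the result was seen. The test of array quality for CLK genes was written before its result.

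All 4 CLK kinase genes rose with 2000 nM at 2, 6 and 24 h, with mean shifts of 0.69, 0.53 and 0.21 (54, 54 and 51 of 56 lines higher, adjusted p = 1.60e-05 by permutation at each time). CLK2 rose by 0.36 ± 0.027 (SE, n = 56 lines) at 2 h, beside CLK1, CLK3 and CLK4. At 200 nM their shifts were 0.20 at 2 h (2 rose), 0.15 at 6 h (3 rose) and 0.15 at 24 h (0 passed in limma), higher in 47 of 53, 49 of 56 and 48 of 55 lines. SR splicing factors, the substrates of these kinases, shifted by -0.15 at 2 h (7 of 9 fell, 53 of 56 lines lower) and -0.24 at 6 h (8 fell, 55 of 56 lines), led at 6 h by SRSF7, which fell by 0.64, SRSF3, which fell by 0.36, and SRSF1, which fell by 0.34. At 200 nM the SR factors shifted by -0.047 at 2 h (1 fell, 47 of 53 lines lower) and -0.05 at 6 h (3 fell, 48 of 56 lines lower), but by 0.022 at 24 h (0 passed in limma, 35 of 55 lines higher, adjusted p = 1.28e-02 by permutation), beside the CLK shift of 0.15. At 24 h with 2000 nM, with a shift of -0.037 (37 of 56 lines lower, adjusted p = 6.53e-03 by permutation), they went both ways, with SRSF6 up by 0.20, SRSF5 up by 0.18, SRSF7 down at -0.28 and SRSF1 at -0.19 (3 rose, 4 fell, and 2 rose with arrays centred on their medians).

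Histone genes of the replication-dependent clusters shifted by 0.11 at 24 h with 2000 nM (11 of 40 rose and 1 fell), with H2AC6 up by 1.02, H2BC5 by 0.63, H2BC21 by 0.53 and H2BC12 by 0.52, while H1-3, a linker histone gene, fell by 0.17. With arrays centred on their medians 11 rose and 5 fell. Of 14 KLF transcription factor genes, 5, 7 and 8 rose at 2, 6 and 24 h and 2 fell at 6 h, with shifts of 0.12, 0.10 and 0.15.

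The rise of CLK genes beside the fall of SR factor genes was weighed. Probes shared among CLK paralogs stay open, since each gene had 1 probeset, 0 of those of CLK2 and CLK3 are of the kind designed for a single transcript, and probe sequences were not examined. Array quality was argued against, since with 7 quality measures as covariates 100.3% of the mean CLK rise remained (0.687 before, 0.689 after). Feedback to CLK kinases inhibited by sunitinib is a hypothesis that these data leave open: the rise at 200 nM at 2 h, a shift of 0.197, was seen before the test was written and any cause that grows with dose would give it. Kinase activity and splicing were not measured.

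In 2 lines the change with 2000 nM at 2 h ran against the other lines across the 200 genes of the panel profile, which are not independent replicates (r = -0.71 for IGR-OV1 and -0.64 for MDA-MB-231, median 0.64 over lines, lowest of the rest 0.29). For IGR-OV1 an exchange of the 0 and 2000 nM arrays and an opposite response stay open: the array labelled 0 nM minus that labelled 200 nM had a slope of 0.90 on the panel change, where an exchange asks for 0.5 or more, the array labelled 200 nM minus that labelled 2000 nM had 0.591, within the 200 nM slopes of the other lines (-0.019 to 0.795), and the reverse difference had -0.591. Its RNA quality lay up to 2.86 SD from other arrays, between the limits set, and decides nothing. For MDA-MB-231 the first slope was 1.17, but the array labelled 200 nM minus that labelled 2000 nM had -0.261. That lay over 3 SD below the mean of 0.268 of other lines (SD 0.132), which argued against this exchange. The reverse difference, 0.261, argued only against an opposite response that grows from 200 to 2000 nM. An opposite response already full at 200 nM stays open. Its changes from 0 nM had slopes of -1.17 with 200 nM and -0.91 with 2000 nM. Exchanges of labels that involve its 200 nM array were not tested and stay open. RNA quality stays open too, as GAPDH in its 0 nM array lay 4.49 SD from the others. Both lines followed the panel at 24 h (r = 0.85 and 0.77), and without their 2 h arrays 1093 genes passed with 2000 nM at 2 h in place of 993, though leaving out lines that oppose the mean favours larger counts.

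With 7 array quality measures as covariates, 78 genes passed with 200 nM at 6 h in place of 244, 62 of them shared. All 244 kept their direction, which is no independent support, since they were picked in the same arrays. The median size of their change went from 0.104 ± 0.027 (SE) to 0.085 ± 0.028. In lines not used to pick them, such genes moved a further 0.05 in their direction from 200 to 2000 nM (0.029 to 0.078 over 20 halvings).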
